A study of Mus musculus with 6 samples.

How the data were processed

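RNA-seq was done on 6 striatal samples, 3 WT and 3 Flox for Esrrg, all from mice given the Cre virus. Grouping and library numbers were taken from the sample titles and genotype labels. The authors deposited a table of raw counts of reads per gene with Ensembl gene identifiers. Per the submitters' processing notes, the tools were CASAVA, Trim Galore 0.6.5, STAR 2.7.3a, HTSeq 0.11.3 and DESeq2, with the genome build GRCm38. The notes give no role for each tool. The annotation release, the treatment of reads on either strand and the handling of reads from several places are not given in the sources used here. Per the labels' protocols, the tissue was flash frozen, RNA was extracted with Trizol and libraries were made with standard Illumina protocols. Without strand information, reads of overlapping genes and of antisense partners cannot be told apart, and reads of near-identical copies may be lost or split, which makes counts of gene families and of mitochondrially encoded genes uncertain.

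The 5 summary lines of HTSeq at the end of the deposited counts name no gene and were left out of library sizes and tests. They held between 25.3% and 30.7% of the reads in a library. Reads that overlapped several genes made up between 5.50% and 6.45%. Gene counts per library ranged from 14776802 in Flox 2 to 30033290 in WT 3, so low genes are measured least precisely in Flox 2. The 10 most abundant genes took between 6.11% and 6.99% of gene reads. Symbols were found for 55144 of the 56246 identifiers in a table of mouse gene names, and positions came from GENCODE M21 on GRCm38, which holds 55230 of the identifiers. Where several identifiers had the same symbol, the identifier with the most reads kept it, and the other 107 were listed by identifier.

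Counts were analysed in R 4.3.3. Genes were filtered with filterByExpr on the groups and scaled with TMM in edgeR 4.0.16. The main test was edgeR's quasi-likelihood F-test on genotype alone, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are log2 of Flox over WT. The SE was derived from the fold change and its F value. CPM values are TMM-scaled unless stated otherwise. Plots were drawn with matplotlib 3.10.9.

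The 35 gene lists were chosen from general knowledge before the data were examined, and cover ERR biology, energy metabolism, neuronal classes, other cell types of the region and stress responses. Each was tested on voom values with camera in limma 3.58.1, at a preset inter-gene correlation of 0.01 with Benjamini-Hochberg adjustment over the lists, and with fry. All 35 lists had at least 5 tested members. Camera was repeated with an estimated correlation, and none of the 13 calls held there. Medians of lists are from voom unless edgeR is named. List members were also adjusted over the list alone. Lists overlap, so their results are not independent.

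The rule for named genes was also set before the data were examined. Esrrg was always named, then up to 12 rises and 12 falls by fold change among genes with an adjusted p under 0.05, a mean CPM of at least 1 and ranges that do not overlap. Because fewer than 10 genes passed, the 10 genes with the smallest unadjusted p were named too. In each list up to 4 members with the smallest p were named. Genes known only by a model name were counted and not named. Regional, choroid plexus, spiny neuron, sex-linked, immunoglobulin, milk protein and clock genes, the list members that did not pass among the immediate early genes, and the remaining members that fell over the list alone were named after their values were seen.

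The test was run on simulated counts drawn from the means and library sizes of these libraries, with 18121 genes. The changed genes were drawn only from those with a mean CPM of at least 1, so recovery below that level was not measured. The test recovered 41.8% of genes changed by 1.5-fold, 71.6% by 2-fold and 97.0% by 4-fold, with 14 false calls among 17921 unchanged genes. With the complex I list lowered by 1.15-fold in simulated data, that list was called and 1 of 34 other lists was called falsely. Simulated genes were drawn independently and with the same mean in all libraries of a group. The simulation thus holds no correlation between genes and no difference in tissue between libraries. It does not measure how often lists are called falsely in the real libraries.

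The alternatives set in advance were DESeq2 1.42.0, RLE and upper-quartile scaling, no low-count filter, a mean CPM of at least 1, limma voom, an adjusted p under 0.1, the library number as a block, leaving out each library in turn, and for lists the estimated correlation. After seeing the data, a fit with WT 1 and WT 3 summed to 1 sample and a fit with the mean log2 CPM of the cortical list as a covariate were added. The other scalings moved the median log2 fold change of all genes from -0.01 to between -0.01 and -0.02. Nothing from the deposited table was left out other than the summary lines and the genes removed by the filter.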

Results

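Striatal RNA was profiled by sequencing in 6 libraries from C57BL/6 mice aged 4 months. The striatum is a forebrain nucleus made up mostly of GABAergic spiny projection neurons. Esrrg encodes estrogen-related receptor gamma (ERR gamma), an orphan nuclear receptor that acts on genes of mitochondrial energy metabolism. All animals were given an adeno-associated virus that carries Cre under a Camk promoter, so that Cre removes a floxed allele in the neurons that express it. The 3 WT libraries came from mice with the wild-type Esrrg allele and the 3 Flox libraries from mice with the floxed allele, 1 month after deletion. The deposited table held raw counts of reads per gene. Gene counts summed to 17818990, 22122994 and 30033290 in WT 1, WT 2 and WT 3, and to 21705407, 14776802 and 28964333 in Flox 1, Flox 2 and Flox 3. Of 56246 genes in the table, 34618 had a read in at least 1 library and 18121 passed the low-count filter and were tested. The common biological coefficient of variation was 0.158. Nothing in the labels says that the libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may in part be technical.

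The first question was whether the targeted transcript was lower in the Flox striatum. Esrrg (ENSMUSG00000026610.13, GRCm38 chromosome 1, 187608791 to 188214885, plus strand, protein-coding) was not shown to differ between the groups. It stood at 30.6, 54.5 and 29.3 CPM in WT 1, WT 2 and WT 3, and at 26.1, 34.3 and 34.9 CPM in Flox 1, Flox 2 and Flox 3. The mean was 38.1 ± 14.2 CPM (SD, n = 3) in WT and 31.8 ± 4.87 CPM (SD, n = 3) in Flox. The fitted log2 fold change was -0.26 with an SE of 0.24, and the adjusted p of edgeR's quasi-likelihood test was 0.923. Without WT 2, the library with the highest value, the log2 fold change was 0.09 (adjusted p = 0.804). These counts cover the whole gene, including exons outside any deleted part, and the tissue holds cells that do not express Cre, so the values neither check nor go against the group labels.

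The second question was which transcripts differed 1 month after deletion. Per2 and Fos were higher in Flox, and no gene was lower, at an adjusted p under 0.05. Per2 (ENSMUSG00000055866.9, chromosome 1, 91415982 to 91459324, minus strand), a repressor in the circadian clock whose promoter also responds to calcium and cyclic AMP signalling, rose from 62.7 ± 3.68 CPM (SD, n = 3) to 129 ± 11.8 CPM (SD, n = 3), a log2 fold change of 1.04 with an SE of 0.09. Fos (ENSMUSG00000021250.13, chromosome 12, 85473890 to 85477273, plus strand), a transcription factor gene induced within minutes of neuronal activity, rose from 7.67 ± 0.424 CPM (SD, n = 3) to 18.1 ± 1.48 CPM (SD, n = 3), a log2 fold change of 1.24 with an SE of 0.11. The adjusted p was 0.0326 for both genes in edgeR's quasi-likelihood test, and all 3 Flox libraries lay above all 3 WT libraries. The next genes by p did not pass in the main test. Arc, whose product acts at synapses to remove AMPA receptors, stood at 107 CPM in WT and 205 CPM in Flox (log2 fold change 0.94, adjusted p = 0.0796). Egr1, an activity-induced zinc finger factor, stood at 198 and 395 CPM (log2 fold change 0.99, adjusted p = 0.0945). Midn, Nr4a1, Egr4, Nr4a3 and Junb followed with positive log2 fold changes of 0.62, 1.02, 0.97, 1.73 and 0.80, and the cadherin gene Cdh7 with -0.52, from 29.2 ± 1.38 to 20.4 ± 1.05 CPM (SD, n = 3 each). In all 8 of these genes the Flox libraries lay wholly on the same side of the WT libraries, and each of the 8 was called with DESeq2, with no low-count filter, without WT 2 and with the cortical covariate, a fit chosen after the data were seen. Adjusted p in these 4 fits ran from 1.61e-12 to 0.00682 for Arc, from 9.81e-13 to 0.00787 for Egr1 and from 0.0163 to 0.0392 for Cdh7. Without WT 2 the WT group was WT 1 and WT 3, the closest pair of libraries, both with near 0 Y-linked reads. Genotype and Y-linked reads could then not be told apart. That fit and the covariate fit also called the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty higher and Xist lower.

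**Figure D1:**
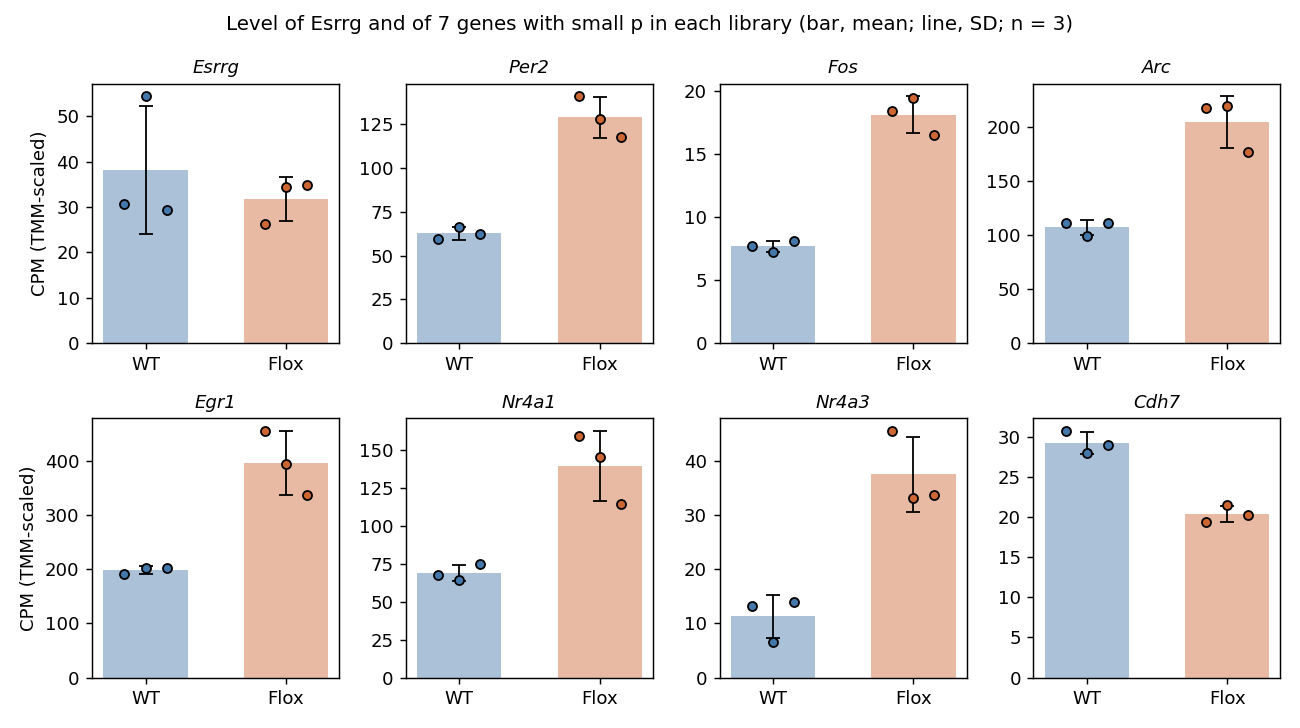
CPM (vertical axis, TMM-scaled) of Esrrg, Per2, Fos, Arc, Egr1, Nr4a1, Nr4a3 and Cdh7 in WT and Flox striatum; points are libraries, bars are means and lines are the SD over 3 libraries. The WT and Flox points of Esrrg overlap, whereas all Flox points lie above the WT points for Per2, at means of 62.7 and 129 CPM, and below them for Cdh7.

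At an unadjusted p under 0.05, 568 genes were higher and 478 lower in Flox, 1046 in all, where 0.05 of the genes tested is 906. The 9 other ways to part the libraries into 3 and 3 gave 218 to 2407 such genes, and 3 of them gave more than the real groups, so the count is no evidence of an excess. It was 2641 without WT 2 and 640 without WT 1. All 3 Flox libraries lay above all 3 WT libraries for 1221 genes and below them for 1057, and chance gives 906 on each side on average. How far that number spreads when genes move together was not measured. The count of changed genes rested on the libraries used and on the tool. DESeq2 called 29 genes (22 higher, 7 lower), Per2 and Fos among them, and edgeR without WT 2 called 153 (60 higher, 93 lower). Leaving out any other library left 0 calls, with adjusted p from 0.0545 to 0.339 for Per2. With WT 1 and WT 3, the closest pair of libraries, summed to 1 sample, a fit chosen after the data were seen, edgeR called 0 genes, and 589 had an unadjusted p under 0.05. Per2 and Fos then had an adjusted p of 0.262 each, at log2 fold changes of 1.02 and 1.25.

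Among the 35 gene lists fixed before the data were examined, the immediate early genes, which neurons transcribe within minutes of stimulation, had the smallest adjusted p and rose as a group. Of 20 members, 19 were tested, and all 19 had a positive log2 fold change, with a median of 0.80. Over all genes tested only Fos passed, and 14 members rose when adjusted over the list alone. Over all genes, 9 members passed with DESeq2, 11 with no low-count filter, 8 without WT 2 and 9 with the cortical covariate, but 0 with voom, the library number as a block, WT 1 and WT 3 summed, or any other library left out; over the list alone between 13 and 16 rose in these fits. In these 14 genes the Flox libraries lay above all WT libraries. They included the orphan nuclear receptor Nr4a1, from 68.8 ± 5.58 to 139 ± 23.0 CPM, Arc and Egr1. Nr4a2, Jun, Ier2, Bdnf and Btg2 did not pass over the list alone. The list had an adjusted p of 9.81e-28 in limma's camera with a preset inter-gene correlation of 0.01. The adjusted p was 0.439 with an estimated correlation, so that call was lost. With fry, which asks whether the members move on balance in a common direction, the p was 0.00326. The mean log2 CPM of the list was 4.89, 4.59 and 4.93 in WT 1, WT 2 and WT 3 and 5.72, 5.54 and 5.42 in Flox 1, Flox 2 and Flox 3. Reads of 4 Y-linked genes were near 0 in WT 1 and WT 3 and present in WT 2 and in all Flox libraries, so the group with higher levels also held more Y-linked reads.

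**Figure D2:**
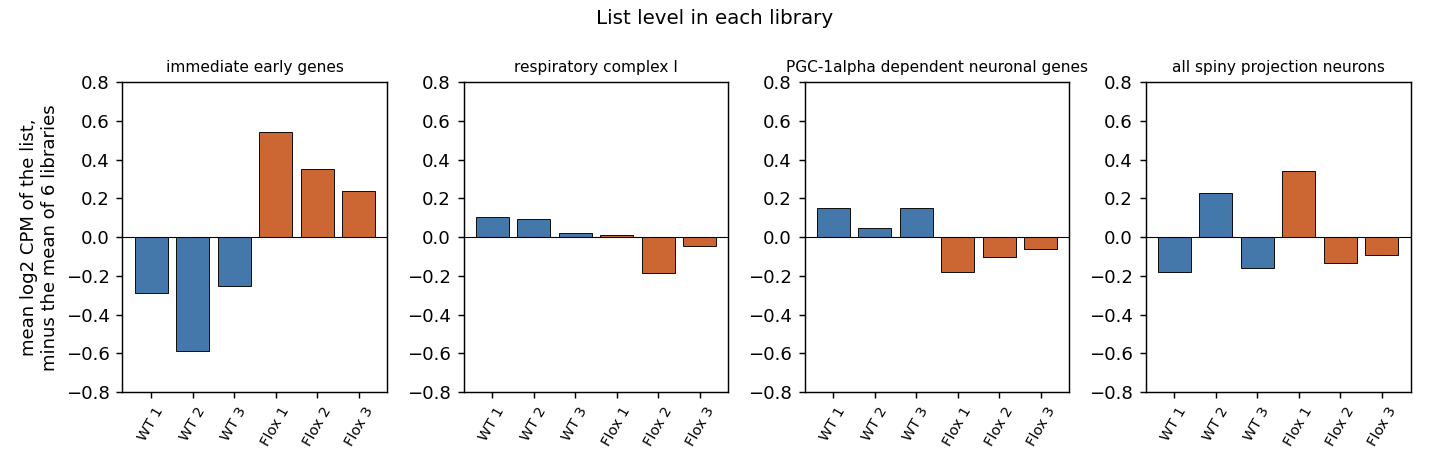
Mean log2 CPM of 4 gene lists in each library (vertical axis, minus the mean of the 6 libraries), with WT in blue and Flox in orange. The immediate early genes lie between 4.59 and 4.93 in the WT libraries and between 5.42 and 5.72 in the Flox libraries, whereas the spiny projection neuron list is highest in WT 2 and Flox 1.

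Genes of the respiratory chain were lower in Flox by small amounts, beside a weaker trend with transcript length. In 5 groups of about equal size by length of the tested coding genes outside the chain, the median log2 fold change ran from -0.05 in the shortest to 0.02 in the longest; it was -0.06 in genes matched to the chain on length and expression, -0.08 in ribosomal protein genes and -0.15 in the chain. In complex I, which passes electrons from NADH to ubiquinone, 34 of 35 tested members had a negative log2 fold change, with a median of -0.13 in voom (adjusted p = 1.12e-08 with camera, and 0.475 with an estimated correlation). The edgeR median of complex I was -0.15, and -0.09 without Flox 2. In complexes II to IV with cytochrome c, all 24 tested members were negative, with a median of -0.16 (adjusted p = 2.74e-10, and 0.475 with an estimated correlation). All 15 tested members of ATP synthase were negative as well, with a median of -0.14 (adjusted p = 1.67e-06, and 0.475 with an estimated correlation). No member of these lists passed over all genes or when adjusted over the list alone in the main test; in complexes II to IV, 8 fell over the list alone without Flox 1 and 2 with the cortical covariate. Cox4i1 stood at 214 ± 6.39 CPM in WT and 182 ± 8.49 CPM in Flox, Cox5a at 46.1 ± 3.68 and 37.7 ± 2.74 CPM, and Ndufv3 at 40.5 ± 1.20 and 35.6 ± 1.18 CPM (SD, n = 3 each). All 3 Flox libraries lay below all 3 WT libraries in 10 members of complex I, 10 of complexes II to IV and 4 of ATP synthase. Chance gives 1 in 20 on each side for a single gene. Members moved together, with estimated correlations of 0.294, 0.484 and 0.444 in these lists, so the counts do not measure an excess. Of the transcripts encoded in the mitochondrion, 11 of 12 tested were negative, with a median of -0.12 (adjusted p = 0.00169, and 0.475 with an estimated correlation). Among them, mt-Nd2 stood at 4387 CPM in WT and 3943 CPM in Flox, and mt-Nd4l at 0.844 and 0.339 CPM, a log2 fold change of -1.37. Reads of these genes can be shared with near-identical nuclear copies and with overlapping neighbours, so their counts are uncertain. The calls of these 4 lists were thus lost with an estimated correlation. The direction of the median was the same under the other 2 scalings. With fry the p was 0.0686 for complex I and 0.0478 for complexes II to IV. It was 0.0776 for ATP synthase and 0.00963 for the mitochondrially encoded genes.

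The neuronal genes that depend on the ERR coactivator PGC-1alpha were also lower. Of 15 tested members, 12 had a negative log2 fold change, with a median of -0.20 in voom (adjusted p = 3.93e-06 with camera; adjusted p = 0.439 with an estimated correlation). Over all genes none passed in the main test, while 1 fell with DESeq2, 2 with no low-count filter, 2 without WT 2 and 1 with the cortical covariate. Over the list alone 6 fell. They were Nefm, a neurofilament subunit, from 213 ± 3.55 to 176 ± 8.03 CPM, Pvalb, the calcium buffer of fast-spiking interneurons, from 33.7 ± 6.73 to 19.5 ± 4.49 CPM, Cplx1, a clamp of vesicle release, from 512 ± 45.2 to 418 ± 11.5 CPM, and Kcnab3, Ndufa4 and Syt2 (SD, n = 3 each). That count over the list alone was 8 with the cortical covariate, 7 with no low-count filter, 5 with DESeq2 or voom, 0 without WT 1, WT 3 or Flox 2 and 3 without Flox 1 or Flox 3, 1 with the library number as a block and 0 with WT 1 and WT 3 summed, while the call of the list was kept at the preset correlation. The edgeR median of the list was -0.21, and -0.11 without WT 1. Its p with fry was 0.0106. The ERR target genes known from textbooks shared 15 of 20 tested members with other lists, most of them mitochondrial. Of the 20, 18 were negative with a median of -0.07, and none passed over the list alone (adjusted p = 0.00578, and 0.822 with an estimated correlation). Cycs, which encodes cytochrome c, stood at 69.0 ± 2.08 CPM in WT and 61.3 ± 4.05 CPM in Flox. Without Flox 2 the adjusted p of this list was 0.287, and its edgeR median, -0.07 with all libraries, was -0.04 without Flox 2 and -0.10 without Flox 1. The p of the ERR target list with fry was 0.189. The ERR receptors and coactivators were not called. Of 14 tested, 10 were positive, with a median of 0.05 (adjusted p = 0.115). Ncoa3, Pprc1, Ppargc1b and Sirt1 each had all Flox libraries above all WT libraries, at log2 fold changes of 0.16, 0.25, 0.19 and 0.16.

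Among other metabolic lists, the citric acid cycle was lower, with 21 of 25 members negative and a median of -0.06 (adjusted p = 0.00401, and 0.475 with an estimated correlation), and no member passed over the list alone. Its adjusted p was 0.0518 without WT 2 and 0.0824 without Flox 2, and its p with fry was 0.0343. In fatty acid oxidation 16 of 21 members were negative, with a median of -0.07 and none passing over the list alone (adjusted p = 0.0164, and 0.840 with an estimated correlation). That call was lost without Flox 2 (adjusted p = 0.0791), and the direction turned without WT 2 (adjusted p = 0.996), with an edgeR median of 0.03 against -0.10 with all libraries. It was also lost with the cortical covariate, chosen after the data were seen (adjusted p = 0.0815). The p of fatty acid oxidation with fry was 0.369. Antioxidant genes were not called, with 15 of 18 negative (adjusted p = 0.0537), though Prdx5 stood at 107 ± 2.71 CPM in WT and 92.6 ± 0.981 CPM in Flox (SD, n = 3 each). Glycolysis had 11 of 16 negative (adjusted p = 0.298). Of 17 cholesterol synthesis genes 10 were negative (adjusted p = 0.424), and Insig1, which retains the sterol sensor in the endoplasmic reticulum, fell when adjusted over the list alone, from 65.3 ± 4.72 to 52.5 ± 1.60 CPM (SD, n = 3 each). No member of that list fell on this measure with DESeq2, RLE scaling, voom, the library number as a block or WT 1 and WT 3 summed, nor without WT 1, WT 3, Flox 1, Flox 2 or Flox 3. Glycolysis and cholesterol synthesis were called lower without WT 2 (adjusted p = 0.0330 and 0.0144), glycolysis also without Flox 1 (adjusted p = 0.0284), and the antioxidant list without WT 1, WT 3 or Flox 1 (adjusted p = 0.0381, 0.00796 and 0.00946). The antioxidant list was also called lower with upper-quartile scaling (adjusted p = 0.0405), at a mean CPM of at least 1 (adjusted p = 0.0490) and with WT 1 and WT 3 summed (adjusted p = 0.0256). The integrated stress response had 13 of 19 negative (adjusted p = 0.272) and the p53 response 10 of 16 positive (adjusted p = 0.789).

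Lists of cells outside the neural lineage also differed, with no member passing over its list alone in the main test. Without WT 2, 3 members of the red blood cell list and 3 of the interferon and lymphocyte list rose over the list alone; with the cortical covariate 1 of each rose, and 2 of the meninges and 2 of the endothelial list fell. With no low-count filter 1 red blood cell gene rose and 1 of the meninges list fell. Meninges and fibroblasts were lower, with 13 of 14 members negative and a median of -0.39 (adjusted p = 0.000221, and 0.615 with an estimated correlation). The collagen gene Col3a1 stood at 3.14 ± 0.402 CPM in WT and 1.79 ± 0.439 CPM in Flox (SD, n = 3 each). Without Flox 1 the adjusted p was 0.136. The edgeR median was -0.40 with all libraries, -0.21 without WT 2 and -0.20 without Flox 1. Endothelial cells and pericytes had 13 of 16 negative with a median of -0.12 (adjusted p = 0.00840, and 0.615 with an estimated correlation). That adjusted p was 0.327 without WT 2 and 0.0707 without Flox 3, and the edgeR median was -0.11 with all libraries and -0.07 without WT 2. Red blood cell genes were higher, with 5 of 7 positive and a median of 0.23 (adjusted p = 0.0419, and 0.511 with an estimated correlation). Leaving out WT 1, WT 3, Flox 1 or Flox 3 raised the adjusted p to between 0.0521 and 0.163, and the edgeR median was 0.20 with all libraries, 0.35 without WT 2 and 0.11 without WT 3. The interferon and lymphocyte list was higher, with 10 of 17 positive and a median of 0.13 (adjusted p = 0.0498, and 0.851 with an estimated correlation). The interferon-induced Irf9 stood at 15.9 ± 2.47 CPM in WT and 20.8 ± 1.40 CPM in Flox (SD, n = 3 each). Without WT 1, WT 3, Flox 2 or Flox 3 its adjusted p lay between 0.0699 and 0.972, and it was 0.0554 under RLE scaling, 0.0649 with no low-count filter, 0.0598 at a mean CPM of at least 1 and 0.0595 with WT 1 and WT 3 summed. Its edgeR median was 0.07 with all libraries, -0.01, 0.43 and -0.10 without WT 1, WT 2 and WT 3, and 0.17, 0.02 and 0.02 without Flox 1, Flox 2 and Flox 3. With fry the p was 0.205 for meninges and fibroblasts and 0.134 for endothelial cells and pericytes. It was 0.0698 for red blood cell genes and 0.540 for the interferon and lymphocyte list.

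**Figure D3:**
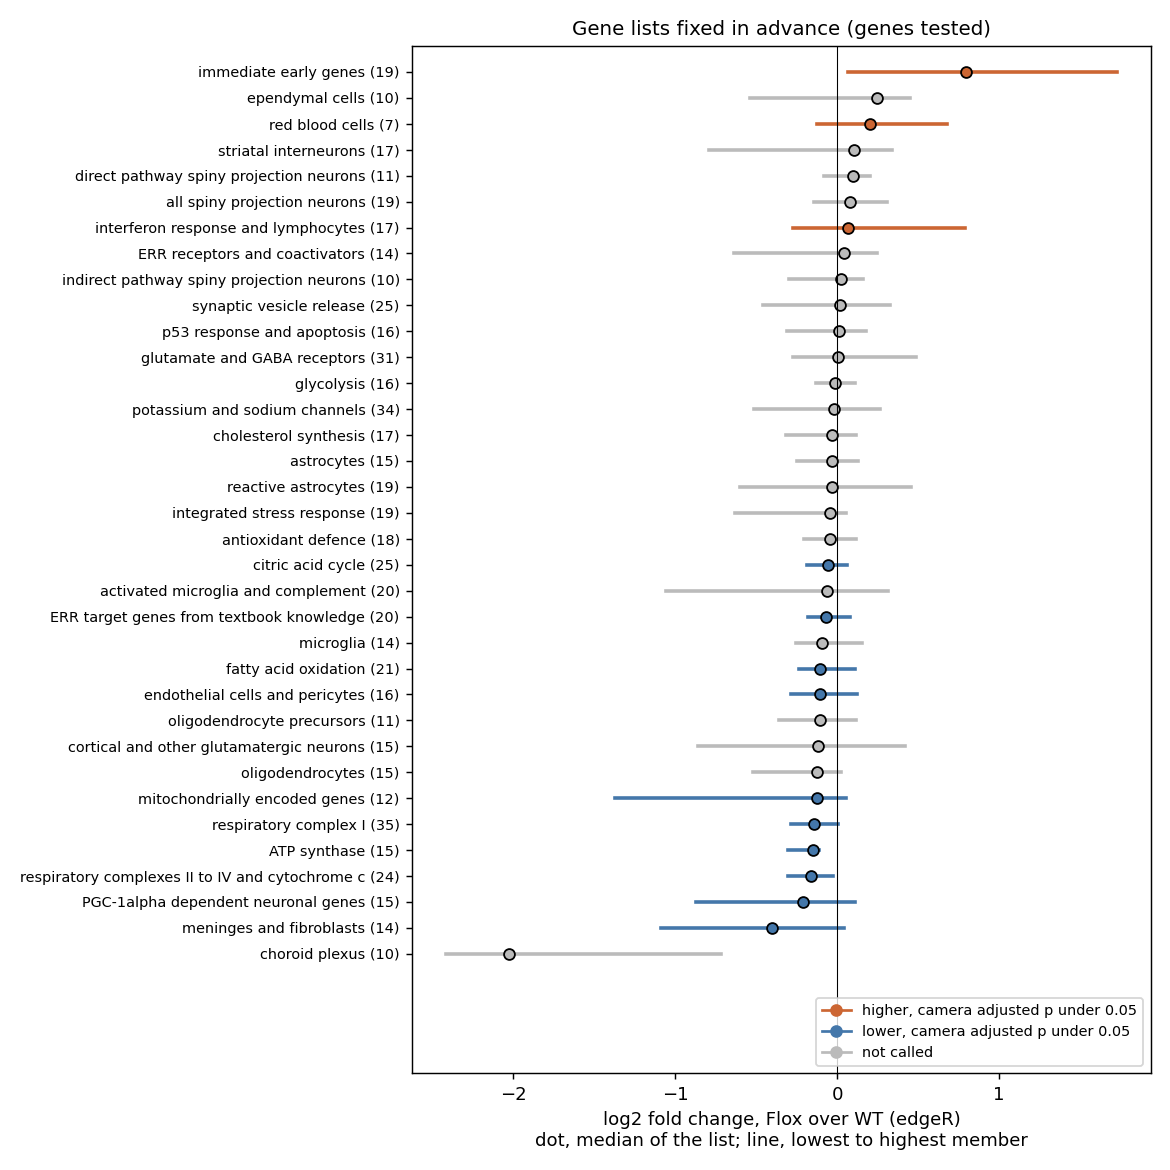
Log2 fold change of Flox over WT (horizontal axis) for the 35 gene lists, as the median (dot) and the lowest to highest tested member (line), with the number of genes tested in brackets; orange and blue mark lists called higher or lower by camera at a preset correlation, and grey marks the rest. The immediate early genes have the highest median at 0.80, and none of the 13 called lists is called with an estimated correlation.

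Markers of the striatal projection neurons were not shown to differ in the main test, and whether their lists were called depended on the libraries and covariate used. The common spiny projection neuron list had 16 of 19 members positive with a median of 0.07 (adjusted p = 0.166), the direct pathway list 7 of 11 (adjusted p = 0.298) and the indirect pathway list 5 of 10 (adjusted p = 0.956, with a negative direction in camera and a median of 0.03). Tac1, a peptide precursor of direct pathway neurons, stood at 123 ± 28.7 CPM in WT and 141 ± 39.7 CPM in Flox, and the dopamine receptor gene Drd2 at 185 ± 42.0 and 202 ± 36.3 CPM (SD, n = 3 each). The interneuron list had 10 of 17 positive (adjusted p = 0.166), with Pvalb as above and Lhx6, which specifies the same lineage, at a log2 fold change of 0.31. Synaptic vesicle release genes had 14 of 25 positive (adjusted p = 0.703), potassium and sodium channels 19 of 34 negative (adjusted p = 0.426), and glutamate and GABA receptors 16 of 31 positive (adjusted p = 0.666). The potassium channel gene Kcnk2 stood at 104 ± 8.73 CPM in WT and 72.6 ± 10.6 CPM in Flox and the sodium channel gene Scn1a at 205 ± 27.6 and 161 ± 11.9 CPM (SD, n = 3 each). The receptor subunit gene Gabra2 had a log2 fold change of 0.49, and no member of these lists passed over its list alone in the main test. Without WT 2, 8 interneuron genes rose and 4 fell over the list alone, 1 channel gene rose and 8 fell, and in both the receptor and the vesicle release list 3 rose and 7 fell, while 1 spiny projection neuron gene rose and 1 indirect pathway gene fell. With the cortical covariate 1 channel gene rose and 7 fell, 4 receptor genes rose and 6 fell, 3 vesicle release genes rose and 3 fell, and 1 interneuron and 1 indirect pathway gene fell. Without Flox 1 a channel gene fell, without Flox 3 a vesicle release gene fell, and the other settings gave at most 2 in any of these lists. Without WT 2 the spiny projection neuron list was called higher (adjusted p = 0.000133), as was the direct pathway list (adjusted p = 0.0246). The spiny projection neuron list was called lower without Flox 1 (adjusted p = 0.0295) and higher without Flox 2 (adjusted p = 0.00435) or Flox 3 (adjusted p = 0.0156). Without WT 2 the channel list (adjusted p = 0.00167) and the vesicle release list (adjusted p = 0.0330) were called lower. With the cortical covariate, chosen after the data were seen, the spiny projection neuron (adjusted p = 0.000314) and direct pathway (adjusted p = 0.0349) lists were called higher and the channel list lower (adjusted p = 0.0224).

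The libraries differed in regional markers in ways the groups do not explain, given here as CPM before TMM scaling. Slc17a7, the vesicular glutamate transporter of cortical neurons, stood at 86.2 CPM in WT 2, at 818 and 804 CPM in WT 1 and WT 3, and at 471, 669 and 557 CPM in Flox 1, Flox 2 and Flox 3. Ttr, the most abundant transcript of the choroid plexus, stood at 2240 CPM in WT 2 and 377 CPM in Flox 3, against 2.64 and 2.16 CPM in WT 1 and WT 3 and 10.5 and 25.7 CPM in Flox 1 and Flox 2. The cortical list was not called (adjusted p = 0.592). Of its 15 members 11 were negative in edgeR, with a median of -0.12, while the median in voom was 0.34. This list was called lower without WT 2 (adjusted p = 3.44e-06; 1 member rose and 8 fell over the list alone, and 2 fell with the cortical covariate) and higher without WT 3 (adjusted p = 0.0425). The choroid plexus list was not called either (adjusted p = 0.789). All 10 tested members were negative in edgeR, with a median of -2.03, while the voom median was 0.13. The choroid plexus list was called higher without WT 2 (adjusted p = 0.000114), where 8 members rose over the list alone. With no low-count filter 10 of 14 tested members fell over the list alone. The list was called lower without WT 3 (adjusted p = 0.0330) or with the library number as a block (adjusted p = 0.0282). The summed CPM of 4 Y-linked genes was 0.112 and 0.166 in WT 1 and WT 3, 65.7 in WT 2, and 89.3, 93.7 and 67.2 in Flox 1, Flox 2 and Flox 3. Xist, which is transcribed from the inactive X chromosome, was present in all 6 libraries at 546 to 1367 CPM. WT 1 and WT 3 were the closest pair, with a correlation of log2 CPM across genes of 0.991 and a mean chi-square per gene of 3.64 against 6.15 to 48.7 in the other pairs, more than counting noise alone. Separate preparations from the same animal would exceed that noise too, so the values do not show that the libraries are independent; they were kept as 2 samples in the main test and summed in an alternative.

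**Figure D4:**
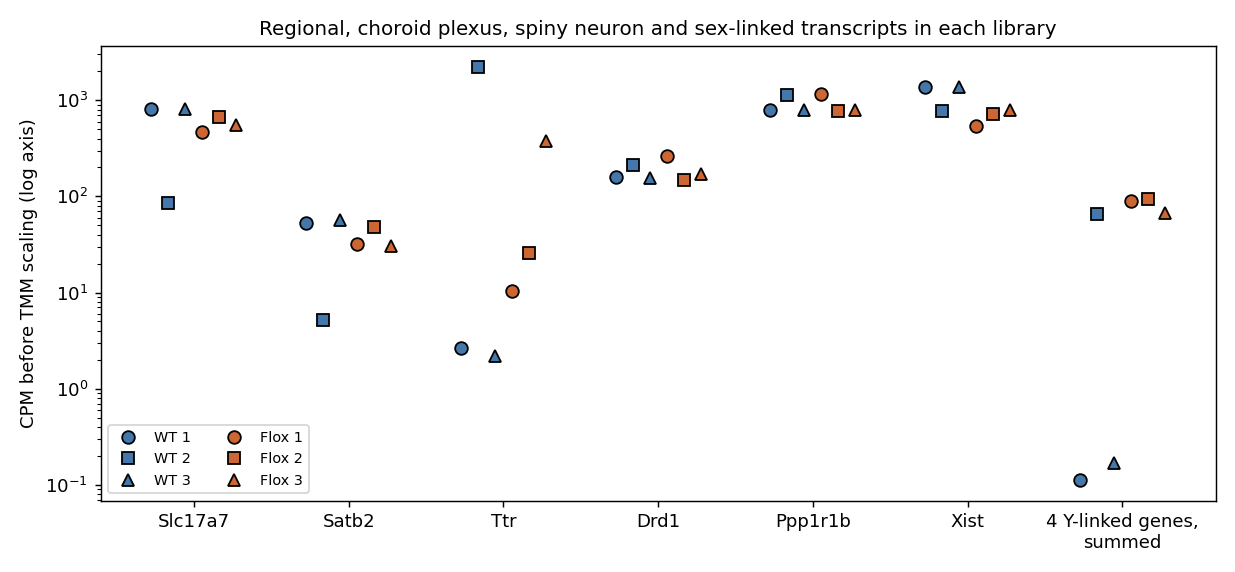
CPM before TMM scaling (vertical log axis) of cortical (Slc17a7, Satb2), choroid plexus (Ttr), spiny neuron (Drd1, Ppp1r1b) and sex-linked transcripts in the 6 libraries, each point a library. WT 2 has the lowest Slc17a7, at 86.2 CPM, and the highest Ttr, at 2240 CPM, and WT 1 and WT 3 have under 1 CPM of Y-linked reads.

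None of the lists of glia or ventricular lining was called in the main test, and no member passed over its list alone there. Without WT 2, 5 ependymal, 4 oligodendrocyte, 1 astrocyte, 1 microglial and 1 activated microglia gene rose over the list alone. With the cortical covariate 5 ependymal genes rose, and 2 activated microglia and 1 precursor gene fell. In the activated microglia list 3 fell with DESeq2 or no low-count filter and 1 without Flox 3; 1 precursor gene fell without WT 3, and 1 oligodendrocyte and 1 precursor gene with no low-count filter. Astrocytes had 10 of 15 members negative (adjusted p = 0.347), with Aldh1l1 at 49.8 ± 2.53 CPM in WT and 41.9 ± 4.98 CPM in Flox (SD, n = 3 each), and reactive astrocytes had 13 of 19 negative (adjusted p = 0.956). Oligodendrocytes had 14 of 15 negative (adjusted p = 0.117), and their precursors 7 of 11 (adjusted p = 0.166), with Olig2 at 30.5 ± 3.76 and 23.8 ± 0.275 CPM (SD, n = 3 each). Microglia had 10 of 14 negative (adjusted p = 0.149). In the activated microglia and complement list 13 of 20 were negative (adjusted p = 0.344), and its members H2-Aa, H2-Ab1 and Cd74, of antigen presentation on MHC class II, had log2 fold changes of -1.06, -1.05 and -0.95 with all Flox libraries below all WT libraries. Ependymal cells had 7 of 10 positive (adjusted p = 0.133). Without WT 2 the oligodendrocyte (adjusted p = 0.000360), ependymal (adjusted p = 2.22e-05) and activated microglia (adjusted p = 0.0238) lists were called higher. The oligodendrocyte and activated microglia lists were called lower without WT 1 (adjusted p = 0.000324 and 0.0165), WT 3 (adjusted p = 0.00121 and 0.00624) or Flox 3 (adjusted p = 0.0179 and 0.0156). Microglia were called lower without WT 1 (adjusted p = 0.0230), oligodendrocyte precursors without WT 3 (adjusted p = 0.00398) and astrocytes without Flox 3 (adjusted p = 0.0310). Ependymal cells were called higher with no low-count filter (adjusted p = 0.0325) and with the cortical covariate (adjusted p = 0.0212). With WT 1 and WT 3 summed, oligodendrocytes (adjusted p = 0.000613), microglia (adjusted p = 0.0391) and oligodendrocyte precursors (adjusted p = 0.0408) were called lower. The summed and covariate fits were chosen after the data were seen.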

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

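The fits with WT 1 and WT 3 summed and with the cortical covariate were chosen after the data were seen. The count of 2 changed genes was the same under RLE scaling, upper-quartile scaling and a mean CPM of at least 1. It was 29 with DESeq2 (22 higher, 7 lower), 48 with no low-count filter (25 higher, 23 lower), 1 with limma voom, 4 at an adjusted p under 0.1, 0 with WT 1 and WT 3 summed and 61 with the cortical covariate (34 higher, 27 lower). Leaving out a library gave between 0 and 153 genes, 153 without WT 2 (60 higher, 93 lower) and 0 without any other. The cause was not tested, except that leaving out or summing libraries leaves fewer samples. Y-linked genes and Xist were among the calls without WT 2 and with the cortical covariate. With the library number as a block there were 0 genes and 14 lists. The deviations of libraries with the same number correlated at -0.06, -0.23 and -0.11, and no library correlated best with its own number. WT 1 and WT 3 had much the same correlations with the Flox libraries, and WT 2 had the opposite signs. The deviations thus mostly set WT 2 apart, and they cannot decide whether the numbers pair the libraries. With 0 calls in edgeR, 638 genes had an unadjusted p under 0.05 with the block and 589 with WT 1 and WT 3 summed. Per2 and Fos were both among the calls of DESeq2, the unfiltered fit, the covariate fit and the fit without WT 2, and voom kept Per2. Their log2 fold changes stayed between 0.97 and 1.11 for Per2 and between 1.18 and 1.30 for Fos. Esrrg was not called in any fit, with log2 fold changes from -0.42 to 0.09, positive only without WT 2. Of the other named genes none reversed, where genes uncalled throughout count as the same whatever their sign.

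The count of 13 called lists lay between 12 and 16 under the other scalings, filters, the block, the summed fit and the covariate, between 10 (without Flox 2) and 21 (without WT 2) with a library left out, and was 0 with an estimated correlation. Directions turned in 8 results, and the cause was not tested. The choroid plexus list was called lower with the block (adjusted p = 0.0282) and without WT 3, with adjusted p from 0.000114 to 0.838 over the libraries left out. Without WT 2 the direction turned for fatty acid oxidation (range 0.000374 to 0.996), the cortical list (3.44e-06 to 0.902), activated microglia (0.00624 to 0.899), oligodendrocytes (0.000324 to 0.315) and synaptic vesicle release (0.0330 to 0.899), and without Flox 1 for the spiny projection neuron list (0.000133 to 0.881). Depth was not varied, so which changes it hides was not tested. In simulated data of these library sizes, 41.8% of 1.5-fold changes were recovered, all placed in genes with a mean CPM of at least 1.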

Other observations

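The gene lists in this part, the tests of cortical tissue and sex for the immediate early genes, the fit with WT 1 and WT 3 summed, the tests of the immunoglobulin segments and the test without Flox 2 were chosen after the results were seen. A list of genes that follow the immediate early wave was also higher in Flox as a whole, though not in each member. Of 14 delayed activity-regulated genes 12 had a positive log2 fold change, and 5 rose when adjusted over the list alone, though none passed over all genes. They were Dusp5 (5.70 to 9.31 CPM, log2 fold change 0.71), Dusp4 (4.77 to 7.35 CPM, 0.62), which both encode phosphatases that shut off MAP kinases, the MAP kinase inhibitor Spry4 (log2 fold change 0.58), the regulator of G protein signalling Rgs2 (72.4 to 105 CPM, 0.53) and the secreted peptide precursor Vgf (230 to 281 CPM, 0.29). All 3 Flox libraries lay above all 3 WT libraries in each, as they did in Scg2 (209 and 245 CPM). Inhba and Nrn1 had negative log2 fold changes of -0.06 and -0.28. Nptx2, Crem and Gadd45g, at 0.17, 0.14 and 0.06, were among the members that did not rise over the list alone. The list's adjusted p over 5 lists was 2.81e-07 with camera at the preset correlation and 0.0223 with an estimated correlation. Among 16 circadian clock genes 3 rose over the list alone, Per2, Per1 (179 to 257 CPM, log2 fold change 0.53) and Cry1 (20.8 to 30.8 CPM, 0.57), with an adjusted p of 2.34e-05 for the list and 0.187 with an estimated correlation. Of the 16, 13 had a positive log2 fold change, and in 6 all Flox libraries lay above all WT libraries. Clock genes not driven by calcium or cyclic AMP, among them Dbp (138 CPM in both groups) and Nr1d1 (138 and 132 CPM), were not called with camera (adjusted p = 0.406). Of these 6 genes 5 had a positive log2 fold change. In Per3 (112 and 124 CPM, log2 fold change 0.14) all Flox libraries lay above all WT libraries.

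Ighm and H2-Aa were picked out as single genes after their values were seen. Ighm, the heavy chain of immunoglobulin M, stood at 63.6 ± 21.2 CPM (SD, n = 3) in WT and 32.2 ± 2.21 CPM (SD, n = 3) in Flox, a log2 fold change of -0.98 that did not pass in the main edgeR test (adjusted p = 0.643). It passed in 4 alternatives, with an adjusted p of 0.00113 in DESeq2, 0.000558 with no low-count filter, 0.00902 without WT 2 and 0.00776 with the cortical covariate, and in no other. H2-Aa stood at 7.83 ± 2.25 and 3.70 ± 1.04 CPM (SD, n = 3 each). The WT value of both was highest in WT 2, the library with the most Ttr. Immunoglobulin variable segments went both ways: Igkv16-104 had 415 and 478 reads in Flox 1 and Flox 3 and at most 22 in any other library, and Igkv5-39 had 752 reads in WT 2 and at most 91 in any other library.

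The immediate early genes had a median log2 fold change of 0.80 in edgeR. With the cortical markers as a covariate the median was 0.812. The mean log2 CPM of these markers was 5.37, 3.85 and 5.38 in WT 1, WT 2 and WT 3 and 4.67, 5.29 and 5.18 in Flox 1, Flox 2 and Flox 3. The covariate mostly set WT 2 apart and differed little between the groups, so that fit was a weak test. The overlap of the markers between the groups itself argues against a different share of cortex as the source. With WT 1 and WT 3 summed to 1 sample the median was 0.80 and the adjusted camera p 5.73e-28, but 0.667 with an estimated correlation (0.439 without summing), so the list is not called there either way. For a different clock time at collection, the median absolute log2 fold change over 6 clock output genes was 0.0695. That lies under the bound of 0.26 set from the change in Per2, which argues against a shift as large as that of Per2 in these genes. Per2 also responds to calcium and cyclic AMP, so a smaller shift in clock time stays open. A different mix of sexes stays open: among libraries with Y-linked reads, Flox 1 to 3 against WT 2, the median was 0.837, but WT 2 alone stands for WT there. Also open is arousal or handling before collection, which no label records, beside an effect of the deletion, which may be the source but was not tested apart from it. In the 9 other ways to part the 6 libraries into 3 and 3, the median reached at most 0.42 in size. At the preset correlation camera still called the list in some of them, with an adjusted p as low as 3.11e-07. Mixed groups also dilute any difference between the real groups, so the smaller medians there are no support for it.

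Immunoglobulin variable segments, which differ between B cell clones, were shared by some pairs of libraries. Of segments at 2 CPM or more in either library, 7 of 7 (100%) lay within 3-fold between WT 1 and WT 3, against 1 of 25 (4.00%) between WT 1 and WT 2. Among the other pairs, the share was 55.6% for Flox 2 and Flox 3 and 45.5% for Flox 1 and Flox 3. WT 1 and Flox 2 reached 33.3%, and pairs with WT 2 had the lowest shares, from 0% with Flox 1 to 4.00% with WT 1. Igkv16-104, Ighv5-6, Ighv9-3 and Igkv3-4 were shared within 3-fold by Flox 1 and Flox 3 alone, and Igkv3-2 by Flox 2 and Flox 3 alone. For reads carried over from a library into another, the CPM ratio of a shared segment was set against the upper limit (95% interval) of the lowest ratio among other genes, with read floors of 40 and 100, and over 10 times the limit at both floors, with and without milk protein genes, was asked for. From Flox 3 into Flox 1 the ratio of Igkv16-104 was 1.16, which is 37.7 times the limit of 0.0307 set by Hcrt, so carry-over in that direction is argued against. From Flox 1 into Flox 3 it stays open, as the ratio of 0.863 is 15.3 times the limit at the floor of 40 but 2.03 times at 100. It also stays open between WT 1 and WT 3. Into WT 3 the ratio of Ighv5-17, 0.832, is 47.9 times the limit set by Wap, but without milk protein genes, which are foreign to the tissue and may have entered WT 1 later, 3.56 and 1.63 times; into WT 1 the ratio of 1.20 is 2.58 times the limit. It is a hypothesis that some libraries hold RNA of the same animal or animals, and the replicates would then not be independent. Xist beside Y-linked reads in WT 2 and all Flox libraries may reflect RNA of both sexes in a library. Sharing an animal between libraries would not by itself give that, and the labels give no sex.

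The 74 respiratory chain genes had a median log2 fold change of -0.15, with 73 of them negative and 24 below all WT libraries. Short transcripts were lower in Flox in general: genes matched on length and expression had a median of -0.0641, and ribosomal protein genes a median of -0.08. In 10000 matched draws the lowest median was -0.12. The draws took genes independently, whereas the estimated inter-gene correlation was 0.294 in complex I and 0.484 in complexes II to IV. Medians of correlated genes spread more, so the draws do not set transcript length aside. With the cortical covariate the median of the chain was -0.150, and without Flox 2 it was -0.0986. Flox 2 alone thus does not account for all of it, while length and Flox 2 together were not tested. The covariate fit was a weak test here too. The overlap of the cortical markers between the groups argues against the share of cortex as the whole source. An effect of the deletion is consistent with these values as a hypothesis, and so is a technical trend that the matching does not capture. In another way to part the libraries, with WT 1, WT 2 and Flox 1 on the same side, complex I had a median of -0.10 (adjusted p = 5.87e-08).

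The 6 libraries can be parted into 3 and 3 in 10 ways, too few for a share under 0.05. The real groups gave 2 changed genes and the highest other count was 1, so that 1 of the 10 ways, the real one, gave as many. For lists the real count was 13 and the highest other 21, and 5 of the 10 ways gave as many as the real one. The 21 came with WT 1, WT 3 and Flox 1 on the same side, which sets WT 2 apart from the other WT libraries.

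Milk protein transcripts (Wap, Csn1s1 and Csn2 among 8 genes) summed to 27.6 CPM in WT 1, 2.90 CPM in Flox 1 and 18.5 CPM in Flox 2, and to 0.0904 CPM in WT 2 and 0 in WT 3 and Flox 3. The thalamic gene Shox2 stood at 16.1 CPM in WT 2 and 4.56 CPM in Flox 3 before TMM scaling and was below the level of Flox 3 in the other libraries, and a list of 14 thalamic genes was not called (adjusted p = 0.758), nor was a list of hypothalamic genes with 6 tested (adjusted p = 0.631). Kcnk2, 1.60 Mb from Esrrg on chromosome 1, had a log2 fold change of -0.51 with all Flox libraries below all WT libraries. Of 140 tested genes within 10 Mb of Esrrg, 8 lay below all WT libraries and 7 above, where chance gives 1 in 20 on each side.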
